A study of Mus musculus with 19 samples.

How the data were processed

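Polyadenylated RNA of interstitial macrophages, sorted by flow cytometry from mouse lung, was sequenced in 19 libraries. Per the labels, each library pooled 4 mice, 2 male and 2 female, and started from 20 ng of total RNA isolated with RNeasy Micro columns. The mice were wild type (WT) or carried the SOD3 R213G substitution, and they were kept in normoxia or in hypobaric hypoxia equivalent to 10% inspired oxygen for 4 or 14 days. The libraries fell into 6 groups by genotype and exposure, with 4 libraries for WT normoxia and 3 for each other group.

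The values analysed were the signal the authors deposited as normalized counts, 1 value per gene and library for 22810 genes. Per the submitters' processing notes, FastQC 0.11.9, UMI-tools 1.1.1, Trim Galore 0.6.6, STAR 2.6.1d, SAMtools 1.9, featureCounts 2.0.1 and DESeq2 (version not given) were used with genome build mm10. The annotation release, the strand setting and whether molecular identifiers were used to collapse reads were not given in the sources used here. Within each library every deposited value was a whole multiple of the smallest value above 0, within a tolerance of 0.01 reads (100% of values). Each value was therefore taken as a whole number of reads divided by 1 size factor per library, and the whole reads were recovered. All columns were matched to a sample by its genotype, exposure and the number in the sample description. Gene identifiers were joined to symbols and mm10 coordinates from the GENCODE annotation, which gave a symbol to 99.37% of them.

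Recovered reads per library ranged from 676929 to 2088480 with a median of 1390134, and the 3 lowest libraries held 676929, 848726 and 849167 reads. Counting intervals and floors cover counting error only, since reads need not be independent molecules.

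Genes with a normalized value of at least 10 in at least 3 libraries were tested (9599 genes). The log2 of the value plus 1 was fitted in R 4.3.3 with limma 3.58.1, with 1 coefficient for each of the 6 groups, moderated variances with an intensity trend and 13 residual degrees of freedom. The median residual SD was 0.404 on the log2 scale. Adding 1 before the logarithm makes fold changes of low genes smaller than the ratio of their means. In all, 11 contrasts were tested: each hypoxia time against normoxia and 14 days against 4 days within each genotype, R213G against WT at each exposure, and the interaction of genotype with each time. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a contrast, and a gene was called when that value was under 0.05. The p-values measure the spread between pools of 4 mice, not between single mice.

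The tests, the gene lists, the rule for named genes and the alternatives, except 3 added later, were fixed before the data were examined. The named genes of a contrast were the 10 with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 50 in the higher group, groups that did not overlap (a condition left out for the interaction) and a symbol that is not a predicted model. Up to 4 members with the smallest adjusted p were named for each list that passed its test or held at least 3 called members. Sod3 was named in every library and contrast, and in a contrast without calls the 3 genes with the smallest p in each direction were named. The text gives a part of the named genes, mostly those that kept their call in every fit that left out 1 library of the compared groups. Some genes that met this rule are not reported here.

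Of 38 gene lists fixed, 13 were markers of other cell types that a lung macrophage sort could hold. Some lists share genes, so their results are not independent. The 34 lists with at least 4 tested members were tested with camera of limma on the same fit at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast. Each test was repeated with the correlation estimated from the residuals. Members called were counted over all genes tested and adjusted over the list alone. List scores per library were the mean over members of the log2 value minus the mean of the WT normoxia libraries.

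Where a compared group held 1 to 3 reads of a named gene, the ratio of both groups' normalized reads is given with its exact 95% binomial counting interval. Responses of both genotypes were compared by Pearson and Spearman correlation of log2 fold changes across genes, and the overlap of called genes by Fisher's exact test, two-sided. The hypoxia contrasts of 1 genotype share their normoxia libraries, so the correlation and covariance of 4 and 14 days were set against 20 simulated data sets without an effect and, for WT, the correlation and overlap against the 6 ways of dividing the 4 normoxia libraries between the times.

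Alternatives were edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 on the recovered reads, pseudocounts of 0.5 and 4, no filter and a filter at 50, upper quartile and quantile normalization, a fit of the compared groups alone, array weights, a replicate block by either number in the labels, and leaving out each library in turn. In those last fits, any group left with fewer libraries is assumed to vary like the others. The fits were tested in 3 simulated runs per contrast, whose rates need not hold for low genes or real libraries. With 200 changed genes among 9342, the WT contrast of 14 days recovered 53.7% of 2-fold and 98.7% of 4-fold changes, with 5.38% false calls. At 4 days the R213G contrast recovered 44.3% and 95.3%, the genotype contrast 42.3% and 95.0%, and the interaction 15.7% and 77.3%.

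Of the lists, 4 were left untested because fewer than 4 members passed the filter: B and plasma cell (2 members), T and NK cell (2), platelet and megakaryocyte (1) and mast cell and basophil (0). No library was left out.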

Results

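RNA of sorted lung interstitial macrophages, which reside in the tissue around airways and vessels, was measured in 19 libraries of 4 mice each. The groups were WT normoxia (n = 4), WT after 4 and 14 days of hypoxia, and R213G in normoxia and after 4 and 14 days (n = 3 each). The R213G substitution lies in the matrix-binding region of SOD3, the extracellular superoxide dismutase, and the design text calls 4 days the peak of inflammation and 14 days its resolution. Recovered reads per library ranged from 1119624 to 1390134 in WT normoxia, 676929 to 1659233 in WT at 4 days and 1231946 to 1830105 in WT at 14 days. The R213G groups ranged from 1203405 to 1834306 in normoxia, 848726 to 1928113 at 4 days and 849167 to 2088480 at 14 days. WT 4-day replicate 1, with the fewest reads, lay apart from the other libraries on the first principal component (79.5 against -31.8 to 18.2 in the others). Reads of Gm42418, a locus overlapping ribosomal RNA sequence, took 7.92% ± 2.46 (SD, n = 3) of the values in WT at 14 days and 13.6% ± 0.637 (SD, n = 3) in R213G at 14 days. That share was 14.96% ± 3.59 in WT normoxia, 18.2% ± 7.21 in WT at 4 days, 15.5% ± 7.94 in R213G normoxia and 15.6% ± 8.08 in R213G at 4 days.

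Sod3 (ENSMUSG00000072941, mm10 chromosome 5, 52363791 to 52371418) was detected at 3 to 44 reads per library. Its normalized count was 12.8 ± 4.79 (SD, n = 4) in WT normoxia, 22.5 ± 11.5 (SD, n = 3) in WT at 4 days and 18.7 ± 0.831 (SD, n = 3) in WT at 14 days. In R213G it was 10.5 ± 5.98 in normoxia, 17.3 ± 1.26 at 4 days and 18.8 ± 5.38 at 14 days (SD, n = 3 each). By library the WT values were 13.7, 19.2, 9.84 and 8.47 in normoxia, 18.99, 35.3 and 13.2 at 4 days, and 18.7, 17.9 and 19.6 at 14 days. The R213G values were 15.6, 12.02 and 3.96 in normoxia, 18.3, 15.9 and 17.8 at 4 days, and 21.9, 12.6 and 21.9 at 14 days. Sod3 passed no test: the log2 difference of R213G from WT was -0.37 in normoxia (adjusted p = 0.981), -0.25 at 4 days (adjusted p = 0.848) and -0.03 at 14 days (adjusted p = 0.985). The difference in normoxia became 0.16 without R213G normoxia replicate 3, and that at 4 days became 0.12 without WT 4-day replicate 2. Against normoxia Sod3 differed by 0.72 (SE 0.402, adjusted p = 0.371) in WT and 0.84 (SE 0.43, adjusted p = 0.298) in R213G at 4 days. At 14 days the values were 0.58 (adjusted p = 0.429) in WT and 0.91 (adjusted p = 0.227) in R213G.

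The first comparison asked how WT interstitial macrophages responded at 4 days of hypoxia. Among the called genes named by their size of change, globin transcripts rose most. Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), a beta globin of red cells, rose from 156 ± 102 (SD, n = 4) to 1786 ± 1654 (SD, n = 3) normalized counts, a log2 fold change of 3.31 (SE 0.577, adjusted p = 0.00642). Hba-a2 rose by 3.64 (SE 0.536, adjusted p = 0.00189), although reads of Hba-a1 and Hba-a2, and of Hbb-bs and Hbb-bt, come from near-identical copies and their division between copies is uncertain. Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor of macrophages, rose from 144 ± 27.7 to 320 ± 34.9 (log2 fold change 1.16, SE 0.171, adjusted p = 0.00189). Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), a matricellular protein, rose by 1.80 (SE 0.253, adjusted p = 0.00189) and Mif (ENSMUSG00000033307), a macrophage cytokine, by 1.67 (SE 0.279, adjusted p = 0.00546). Cd5l, an apoptosis inhibitor secreted by macrophages, went from 4.22 ± 1.32 to 56.2 ± 49.1 (adjusted p = 0.00708, while DESeq2 gave it none), and the splicing-related gene Pnisr fell from 187 ± 36.9 to 65.3 ± 36.9 (log2 fold change -1.69, SE 0.301, adjusted p = 0.00722).

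Among the gene lists, the erythroid list rose, with 4 of 5 tested members higher and 1 not passing (5 higher adjusted over the list alone). Its median log2 fold change was 3.33 (adjusted p = 1.83e-10, adjusted p = 0.039 with an estimated correlation). The list of Lyve1-high perivascular macrophages rose, with 2 of 15 members called higher, Cbr2 and Maf, and 8 higher and 1 lower adjusted over the list alone (median 0.69, adjusted p = 7.85e-06, adjusted p = 0.0406 with an estimated correlation). Complement genes rose, with C4b, C1qc and C1qb called among 12 and 6 higher and 1 lower adjusted over the list alone (median 0.58, adjusted p = 0.000145, adjusted p = 0.039 with an estimated correlation). C1qc, a chain of the opsonin C1q, rose from 950 ± 128 to 1930 ± 448, with an adjusted p of 0.0111 that became 0.0502 without WT normoxia replicate 3. Without the same library the adjusted p was 0.125 for Cbr2, 0.059 for Maf, 0.0647 for C4b and 0.0675 for C1qb. Of the fits without 1 library of these groups, Cbr2 kept its call only in that without WT 4-day replicate 1, C4b had 0.114 without WT 4-day replicate 2, and C1qb 0.0696 without WT 4-day replicate 1. Cholesterol synthesis rose as a list with 0 of 14 members called and 2 higher adjusted over the list alone (median 0.40, adjusted p = 0.000257, adjusted p = 0.0274 with an estimated correlation). Lss had a log2 fold change of 1.26 (adjusted p = 0.261), and all 14 members had positive values.

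The other lists that passed at the preset correlation did not pass with the correlation estimated. Cell cycle genes had a median of 0.82, with 1 of 24 called (Mcm2, 1.66, a helicase subunit of DNA replication) and 2 higher adjusted over the list alone (adjusted p = 3.94e-06, adjusted p = 0.0773 with an estimated correlation). Interstitial macrophage identity genes had a median of 0.40, with 3 of 16 called and 5 higher adjusted over the list alone (adjusted p = 2.12e-05, adjusted p = 0.101 with an estimated correlation). Matrix remodelling genes had a median of 0.47, with Timp2 called among 17 and 5 higher adjusted over the list alone (adjusted p = 0.0015, adjusted p = 0.101 with an estimated correlation). Alternative activation genes had a median of 0.45, with 0 of 12 called and 2 higher adjusted over the list alone (adjusted p = 0.00197, adjusted p = 0.101 with an estimated correlation). Arg1, the arginase of alternatively activated macrophages, had a log2 fold change of 3.88 (SE 1.16, adjusted p = 0.09) and did not pass. Mcm2 lost its call without WT normoxia replicate 2 (adjusted p = 0.0526), 3 (0.0959) or 4 (0.0893) or WT 4-day replicate 1 (0.113), and Timp2 without WT normoxia replicate 3 (0.059) or WT 4-day replicate 2 (0.0535). Positive medians were also found for lipid handling (0.30, adjusted p = 0.00509), iron handling (0.36, adjusted p = 0.00509), MHC class II (0.30, adjusted p = 0.00509), chemokines (0.51, adjusted p = 0.00254) and glycolysis (0.16, adjusted p = 0.0074). With an estimated correlation their adjusted p was 0.118, 0.0501, 0.269, 0.101 and 0.101. Oxidative phosphorylation had a median of 0.27 (adjusted p = 0.0187, adjusted p = 0.13 with an estimated correlation), and fibroblast and mural genes one of 0.67 (adjusted p = 0.0187, adjusted p = 0.16 with an estimated correlation).

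Negative medians were found for classical monocyte genes (-0.60, adjusted p = 0.00673), non-classical monocyte genes (-0.64, adjusted p = 0.00185) and immediate early genes, a sign of cell handling (-0.39, adjusted p = 0.000275). With an estimated correlation their adjusted p was 0.315, 0.269 and 0.209, and Nr4a1 was their only called member, a call lost without WT normoxia replicate 2 (adjusted p = 0.0526), 3 (0.0669) or 4 (0.076) or WT 4-day replicate 1 (0.101). Without WT 4-day replicate 1, the MHC class II and glycolysis lists had an adjusted p of 0.0662, classical monocyte genes 0.11 and chemokines and fibroblast genes 0.0607. The fibroblast list also lost its call without WT normoxia replicate 1 (adjusted p = 0.0779), WT normoxia replicate 3 (0.0627) and WT 4-day replicate 2 (0.0594). Oxidative phosphorylation lost its call without WT 4-day replicate 2 (adjusted p = 0.0874) and replicate 3 (0.0727). In the test of all genes, limma called 107 of 9599, 43 higher and 64 lower, with 1618 at an unadjusted p under 0.05 where chance gives 480. The count was 66, 20 and 55 without WT normoxia replicate 2, 3 and 4, and 0 in a fit of the compared groups alone, where 1171 genes had an unadjusted p under 0.05; DESeq2 called 239 and edgeR 95.

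**Figure D1:**
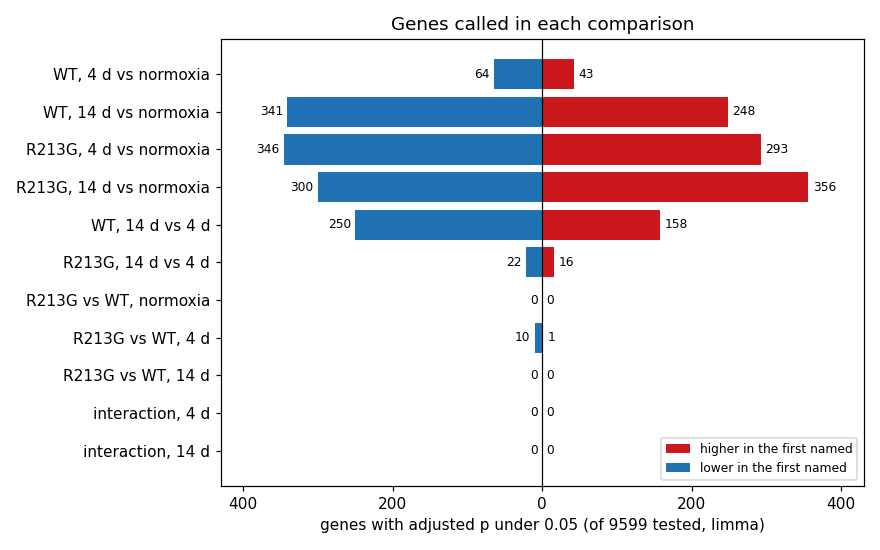
Number of genes called at an adjusted p under 0.05 in each of the 11 comparisons, with those higher as bars to the right and those lower to the left. The bars reach 356 higher and 346 lower genes in the R213G hypoxia comparisons, and 4 of the comparisons have no call.

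The comparison of WT at 14 days with WT normoxia asked which changes were present at the resolution time. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, rose from 11.5 ± 12.7 (SD, n = 4) to 356 ± 363 (SD, n = 3) normalized counts, a log2 fold change of 4.72 (SE 0.713, adjusted p = 0.000509). The cationic amino acid transporter Slc7a2 (ENSMUSG00000031596) rose by 3.55 (SE 0.541, adjusted p = 0.00053), from 14.5 ± 17.1 to 146 ± 95.9. Cd9, a tetraspanin, rose from 230 ± 108 to 1038 ± 154, and Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038), the lysosomal protease cathepsin D, from 1167 ± 482 to 4378 ± 232. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, fell from 494 ± 246 to 132 ± 9.59 (log2 fold change -1.76, SE 0.303, adjusted p = 0.00145). The lysosomal trafficking regulator Lyst fell with a log2 fold change of -1.99 (SE 0.316, adjusted p = 0.000782).

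Genes of lipid handling and lysosomes rose, with 9 of 13 members called higher, 4 not passing and 11 higher adjusted over the list alone. Ctsl had a log2 fold change of 2.75 (SE 0.421), Ctsd 1.99 (SE 0.255) and the lysosomal lipase Lipa 0.96 (SE 0.175), and the list median was 1.05 (adjusted p = 1.83e-11, adjusted p = 0.00418 with an estimated correlation). Iron handling genes rose, with 6 of 9 members higher in both counts, among them the ferritin light chain Ftl1 with 1.69 (SE 0.284). The list had a median of 0.77 (adjusted p = 8.71e-06, adjusted p = 0.00418 with an estimated correlation). Interferon response genes fell, with 11 of 21 members lower, 10 not passing and 17 lower adjusted over the list alone. Zbp1 had a log2 fold change of -1.41 (SE 0.248), Oasl2 -1.38 (SE 0.248) and Irf7 -1.16 (SE 0.222), and the median was -0.98 (adjusted p = 2.62e-13, adjusted p = 0.0262 with an estimated correlation). Matrix remodelling genes rose, with 7 of 17 members higher and 1 lower (7 higher and 2 lower adjusted over the list alone). Mmp12, the macrophage elastase, had a log2 fold change of 1.98 (SE 0.246) and the growth factor Igf1 1.73 (SE 0.243), with a list median of 0.84 (adjusted p = 7.46e-06, adjusted p = 0.035 with an estimated correlation).

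Lyve1-high perivascular genes rose, with 6 of 15 members higher and 1 lower (9 and 1 adjusted over the list alone), among them Pf4 with 1.75 (SE 0.314) and Selenop with 1.16 (SE 0.239). Their median was 1.01 (adjusted p = 1.79e-07, adjusted p = 0.022 with an estimated correlation). Efferocytosis genes, which serve the uptake of dying cells, rose with 2 of 12 called, Cd36 (1.49, SE 0.316) and Gas6 (1.18, SE 0.255), and 3 higher adjusted over the list alone (median 0.49, adjusted p = 0.000725, adjusted p = 0.0442 with an estimated correlation). Complement genes rose, with 3 of 12 higher and 7 higher and 1 lower adjusted over the list alone (median 0.62, adjusted p = 0.000998, adjusted p = 0.0436 with an estimated correlation). Cholesterol synthesis rose, with 2 of 14 higher and 4 adjusted over the list alone (median 0.52, adjusted p = 0.00543, 0.0403 with an estimated correlation). The list of alveolar macrophage genes, a cell type of the air spaces, rose with 3 of 12 higher and 5 adjusted over the list alone, led by Atp6v0d2 with 2.73 (SE 0.371). Its median was 0.74 (adjusted p = 7.22e-05, 0.0403 with an estimated correlation). Interstitial macrophage identity genes had 7 of 16 members higher and 9 adjusted over the list alone, among them Adgre1, the F4/80 antigen, with 0.93 (SE 0.175) and Trem2 with 1.43 (SE 0.171). That list had a median of 0.57 (adjusted p = 9.36e-06, adjusted p = 0.0617 with an estimated correlation).

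Classical monocyte genes had 6 of 13 members lower and 1 higher (7 and 1 adjusted over the list alone). Ly6c2, a surface protein of classical monocytes with close relatives in its family, fell from 1217 ± 202 to 434 ± 68.7. The median was -0.60 (adjusted p = 0.000725, adjusted p = 0.195 with an estimated correlation). Non-classical monocyte genes had 3 of 11 lower and 4 adjusted over the list alone (median -0.63, adjusted p = 0.00308, adjusted p = 0.268 with an estimated correlation). NADPH oxidase genes had 2 of 6 lower and 3 adjusted over the list alone (median -0.42, adjusted p = 0.00371, adjusted p = 0.0545 with an estimated correlation). Immediate early genes had 6 of 15 lower and 8 adjusted over the list alone (median -0.55, adjusted p = 2.3e-05, adjusted p = 0.135 with an estimated correlation). Alternative activation genes had 4 of 12 higher and 6 adjusted over the list alone (median 1.02, adjusted p = 0.000725, adjusted p = 0.0617 with an estimated correlation). Chemokines had 3 of 13 higher and 5 adjusted over the list alone, among them Cxcl16 with 0.90 (SE 0.182). The median over its members was 0.68 (adjusted p = 0.00371, adjusted p = 0.0869 with an estimated correlation). Antioxidant genes had 4 of 18 higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.00543, adjusted p = 0.268 with an estimated correlation).

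The remaining lists called at 14 days in WT were less stable as lists. The neutrophil list had a median of -1.21 (adjusted p = 0.0142, 0.138 with an estimated correlation), lost without WT normoxia replicate 1 (adjusted p = 0.0604) or WT 14-day replicate 1 (0.0558). Inflammatory genes of the NF-kB pathway had a median of -0.30 (adjusted p = 0.0387, 0.268 with an estimated correlation). Their adjusted p was 0.454 without WT 14-day replicate 1, and 0.0583, 0.0588 and 0.0719 without WT normoxia replicate 1, 3 and 4. Unfolded protein response genes had a median of 0.34 (adjusted p = 0.00371, 0.253 with an estimated correlation), lost without WT 14-day replicate 2 (adjusted p = 0.109). Mitochondrially encoded transcripts had a median of 0.51 (adjusted p = 0.0142, 0.0545 with an estimated correlation), lost without WT 14-day replicate 1 (adjusted p = 0.0558). In all, limma called 589 genes, 248 higher and 341 lower, with 2132 at an unadjusted p under 0.05. The count was 329 without WT normoxia replicate 4, and 139 and 186 without WT 14-day replicate 2 and 3. It was 225 with the Gm42418 share as a covariate, where the adjusted p was 0.118 for Cd36, 0.0781 for Gas6, 0.0681 for Selenop and 0.0529 for Cxcl16. Upper quartile scaling gave 291 higher and 266 lower genes.

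The comparison of R213G at 4 days with normoxia asked how R213G macrophages responded at the inflammation peak. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) rose from 3 reads in all 3 normoxia libraries to 1414 reads at 4 days, a ratio of 457 with a 95% counting interval of 156 to 2220. Its log2 fold change was 7.79 (SE 1.24, adjusted p = 0.000761), and its mean at 4 days was 405 ± 31.3 (SD, n = 3) normalized counts. Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), an inhibitor of matrix metalloproteinases, rose from 2 to 208 reads, a ratio of 101 with an interval of 27.6 to 838 (adjusted p = 0.00131). Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364), a membrane-bound matrix metalloproteinase, rose from 35.8 ± 11.6 to 345 ± 85.8 (log2 fold change 3.25, SE 0.40, adjusted p = 0.000185). Spp1 rose from 7.69 ± 2.95 to 183 ± 76.8 and the interleukin-1 receptor antagonist Il1rn (ENSMUSG00000026981) from 16.8 ± 2.04 to 143 ± 51.5. Among genes that fell, the citrullinating enzyme Padi2 went from 148 ± 30.4 to 38.03 ± 16.5 (adjusted p = 0.000309) and the transcription factor Nfe2 from 95.9 ± 15.8 to 24.0 ± 8.81 (adjusted p = 0.00102).

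Matrix remodelling genes rose, with 10 of 17 members higher, 7 not passing and 11 higher adjusted over the list alone (median 1.01, adjusted p = 4.79e-11, adjusted p = 0.00611 with an estimated correlation). Alternative activation genes rose, with 6 of 12 higher and 8 adjusted over the list alone, among them the crosslinking enzyme Tgm2 with 2.59 (SE 0.448) and the mannose receptor Mrc1 with 1.33 (SE 0.219). Their median was 1.33 (adjusted p = 9.86e-09, adjusted p = 0.00611 with an estimated correlation). Chemokines rose, with 7 of 13 higher and 8 adjusted over the list alone, among them the eosinophil attractant Ccl24 with 4.39 (SE 0.868) and Cxcl16 with 1.37 (SE 0.195). The list had a median of 1.37 (adjusted p = 8.69e-08, adjusted p = 0.00611 with an estimated correlation). Lipid and lysosome genes rose, with 6 of 13 higher and 10 adjusted over the list alone, among them the fatty acid binding protein Fabp5 with 2.92 (SE 0.551). Its median was 1.04 (adjusted p = 9.89e-09, adjusted p = 0.00611 with an estimated correlation). Cell cycle genes rose, with 10 of 24 higher and 17 adjusted over the list alone (median 1.40, adjusted p = 2.71e-11, adjusted p = 0.00751 with an estimated correlation). Mcm2 rose from 7.43 ± 3.58 to 36.6 ± 5.46 and the topoisomerase Top2a from 24.0 ± 5.77 to 72.6 ± 5.92 normalized counts.

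Interstitial macrophage identity genes rose, with 8 of 16 higher and 12 adjusted over the list alone, among them Cd63 with 1.77 (SE 0.281) and C1qc with 1.44 (SE 0.2). The median over its members was 0.81 (adjusted p = 8.62e-12, adjusted p = 0.00751 with an estimated correlation). Lyve1-high perivascular genes rose, with 11 of 15 higher and 1 lower in both counts, the coagulation factor F13a1 falling with -1.35 (SE 0.252). Their median was 1.29 (adjusted p = 3.29e-09, adjusted p = 0.00611 with an estimated correlation). Complement genes rose, with 6 of 12 higher and 1 lower (8 and 1 adjusted over the list alone), among them C3ar1 with 1.72 (SE 0.273) and C5ar1 with 1.25 (SE 0.19). The list had a median of 1.26 (adjusted p = 4.92e-07, adjusted p = 0.00611 with an estimated correlation). Efferocytosis genes rose, with 3 of 12 higher and 6 adjusted over the list alone (median 0.81, adjusted p = 9.36e-05, adjusted p = 0.0185 with an estimated correlation). Iron handling genes rose, with 4 of 9 higher and 5 adjusted over the list alone (median 0.65, adjusted p = 0.000418, adjusted p = 0.00751 with an estimated correlation). Immediate early genes fell, with 9 of 15 lower and 14 adjusted over the list alone (median -0.76, adjusted p = 1.27e-12, adjusted p = 0.0156 with an estimated correlation). Nr4a1, an immediate early nuclear receptor, fell from 1777 ± 336 to 526 ± 235, and the heat shock gene Hspa1b, a near-identical copy of Hspa1a, from 479 ± 266 to 48.3 ± 31.9.

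Markers of other cells moved too in R213G at 4 days. Erythroid genes rose, with 4 of 5 members higher and 5 adjusted over the list alone, Hba-a2 rising from 37.0 ± 14.9 to 264 ± 30.4 (median 2.89, adjusted p = 3.61e-07, adjusted p = 0.0395 with an estimated correlation). Fibroblast and mural genes rose, with Mgp called among 7 and 5 higher adjusted over the list alone (median 1.28, adjusted p = 0.000684, adjusted p = 0.0395 with an estimated correlation). Mgp lost its call without R213G normoxia replicate 1 (adjusted p = 0.105) or 3 (0.123) or R213G 4-day replicate 2 (0.15) or 3 (0.12). Classical monocyte genes had 4 of 13 lower and 7 adjusted over the list alone (median -0.98, adjusted p = 9.36e-05, adjusted p = 0.13 with an estimated correlation). Non-classical monocyte genes had 3 of 11 lower and 6 adjusted over the list alone (median -1.12, adjusted p = 3.69e-05, adjusted p = 0.13 with an estimated correlation). MHC class II genes had 4 of 12 higher and 5 adjusted over the list alone, led by the co-receptor Cd72 with 1.98 (SE 0.267). Its median was 0.69 (adjusted p = 8.02e-06, adjusted p = 0.0779 with an estimated correlation). Alveolar macrophage genes had 3 of 12 higher in both counts (median 0.31, adjusted p = 0.0256, adjusted p = 0.158 with an estimated correlation), lost without R213G 4-day replicate 3 (adjusted p = 0.174) or R213G normoxia replicate 2 (0.0933). Glycolysis had a median of 0.12 (adjusted p = 0.0382, adjusted p = 0.121 with an estimated correlation) and oxidative phosphorylation one of 0.24 (adjusted p = 0.0233, adjusted p = 0.121 with an estimated correlation). The glycolysis call was lost without R213G normoxia replicate 1 (adjusted p = 0.0696) or 2 (0.0595) and without R213G 4-day replicate 1 (0.0992) or 2 (0.087). In all, limma called 639 genes, 293 higher and 346 lower, with 1842 at an unadjusted p under 0.05. The count was 378 and 376 without R213G normoxia replicate 1 and 2, and 290 and 355 without R213G 4-day replicate 1 and 2.

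**Figure D2:**
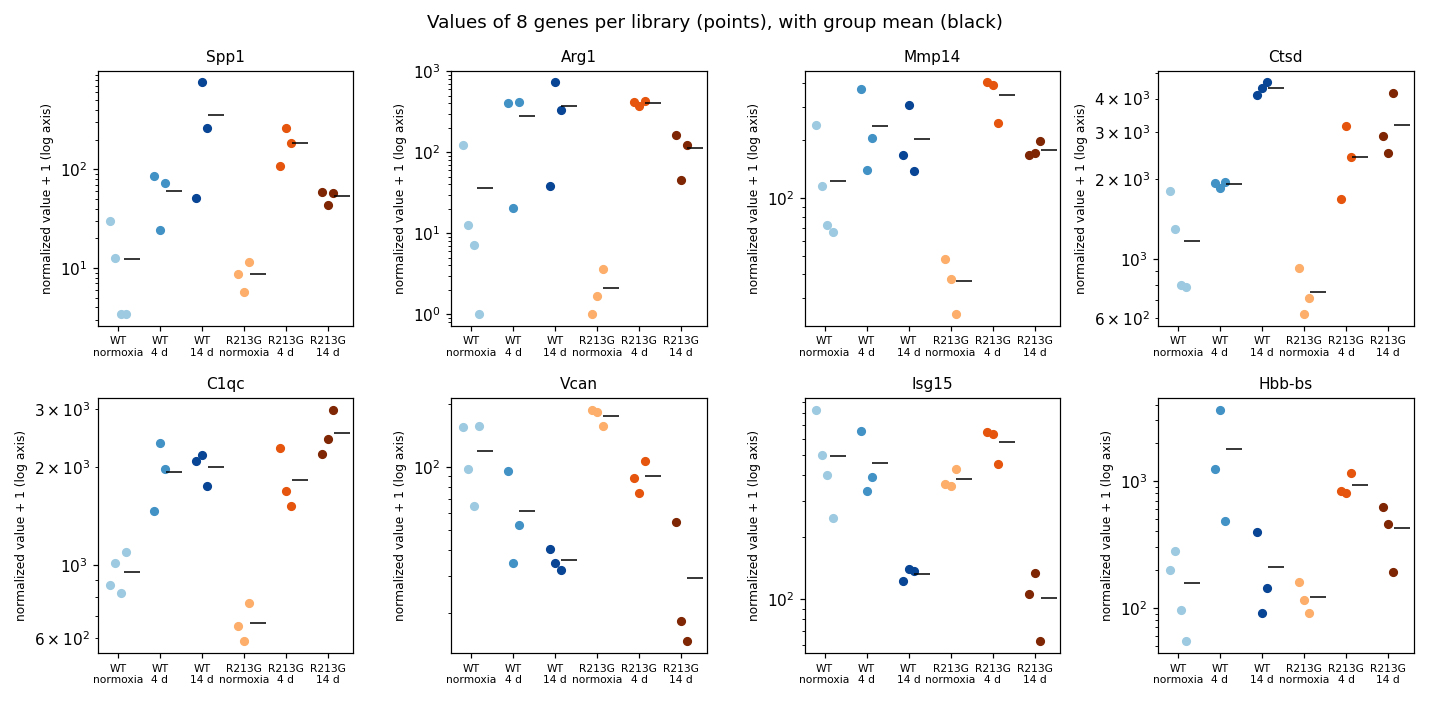
Normalized count plus 1, on a log axis, of 8 genes in each of the 19 libraries by group, with a line at the group mean. Arg1 was 1.103 on average in R213G normoxia and 405 at 4 days, and Mmp14 was 35.8 and 345 in the same groups. In WT normoxia and at 4 days Arg1 was 34.8 and 282, and Mmp14 123 and 238.

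The comparison of R213G at 14 days with normoxia asked what differed at the resolution time. The bone and lysosome protease Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362) rose from 6.32 ± 6.03 (SD, n = 3) to 92.4 ± 6.35 (SD, n = 3) normalized counts, a log2 fold change of 4.31 (SE 0.71, adjusted p = 0.000529). The proton pump subunit Atp6v0d2 (ENSMUSG00000028238) rose from 4.99 ± 0.56 to 61.7 ± 17.9 (log2 fold change 3.36, SE 0.396, adjusted p = 3.33e-05) and the lysosomal glycoprotein Gpnmb (ENSMUSG00000029816) from 14.0 ± 5.15 to 136 ± 38.6. Arg1 rose from 3 to 429 reads, a ratio of 146 with a 95% counting interval of 49.8 to 713 (adjusted p = 0.00561). The proteoglycan Vcan (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509) fell from 175 ± 16.7 to 28.2 ± 22.1 (log2 fold change -2.84, SE 0.402, adjusted p = 0.000185), and haptoglobin, Hp, fell from 805 ± 161 to 187 ± 56.6.

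Classical monocyte genes fell, with 9 of 13 members lower, 4 not passing and 11 lower adjusted over the list alone (median -1.49, adjusted p = 8.14e-11, adjusted p = 0.0243 with an estimated correlation). Ccr2 (ENSMUSG00000049103), the chemokine receptor of recruited monocytes, fell from 1291 ± 351 to 452 ± 82.8. Interferon response genes fell, with 11 of 21 lower and 16 adjusted over the list alone, among them Isg15 from 381 ± 40.5 to 100.4 ± 36.4 (median -1.16, adjusted p = 4.42e-13, adjusted p = 0.0175 with an estimated correlation). Interstitial macrophage identity genes rose, with 10 of 16 higher and 12 higher and 1 lower adjusted over the list alone (median 1.28, adjusted p = 1.8e-11, adjusted p = 0.0155 with an estimated correlation). C1qc rose from 667 ± 91.7 to 2534 ± 412 and Trem2 with a log2 fold change of 1.72 (SE 0.183, adjusted p = 1.67e-05). Matrix remodelling genes rose, with 9 of 17 higher and 1 lower in both counts, among them Mmp14 with 2.33 (SE 0.40) and Igf1 with 1.95 (SE 0.26). The median over its members was 1.54 (adjusted p = 1.81e-07, adjusted p = 0.0155 with an estimated correlation). Lipid and lysosome genes rose, with 7 of 13 higher and 10 adjusted over the list alone, among them Ctsd with 2.07 (SE 0.273) and Apoe with 1.56 (SE 0.252). Their median was 0.88 (adjusted p = 1.02e-08, adjusted p = 0.0114 with an estimated correlation).

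Lyve1-high perivascular genes rose, with 8 of 15 higher and 1 lower (9 and 1 adjusted over the list alone; median 1.08, adjusted p = 1.85e-07, adjusted p = 0.0155 with an estimated correlation). Efferocytosis genes rose, with 6 of 12 higher and 7 adjusted over the list alone, among them the receptor kinase Axl with 1.36 (SE 0.207). The list had a median of 1.06 (adjusted p = 2.93e-05, adjusted p = 0.0175 with an estimated correlation). Iron handling genes rose, with 4 of 9 higher and 5 adjusted over the list alone (median 0.58, adjusted p = 1.87e-05, adjusted p = 0.0114 with an estimated correlation). Complement genes rose, with 6 of 12 higher and 1 lower (6 and 2 adjusted over the list alone), component C3 falling with -1.50 (SE 0.236). Its median was 0.95 (adjusted p = 0.000665, adjusted p = 0.0338 with an estimated correlation). MHC class II genes had 4 of 12 higher and 6 adjusted over the list alone (median 0.75, adjusted p = 7.8e-06, adjusted p = 0.0785 with an estimated correlation). Alternative activation genes had 4 of 12 higher and 5 adjusted over the list alone (median 0.97, adjusted p = 0.000171, adjusted p = 0.0507 with an estimated correlation). Alveolar macrophage genes had 2 of 12 higher and 3 adjusted over the list alone (median 0.92, adjusted p = 0.000709, adjusted p = 0.0658 with an estimated correlation), and chemokines 2 of 13 and 4 (median 1.11, adjusted p = 0.00166, adjusted p = 0.0731 with an estimated correlation). Immediate early genes had 5 of 15 lower and 8 adjusted over the list alone (median -0.75, adjusted p = 2.36e-06, adjusted p = 0.0991 with an estimated correlation). Non-classical monocyte genes had 3 of 11 lower, and 7 lower and 1 higher adjusted over the list alone (median -0.995, adjusted p = 0.000216, adjusted p = 0.2 with an estimated correlation).

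Erythroid genes had 0 of 5 called and 5 higher adjusted over the list alone (median 1.66, adjusted p = 0.00213, adjusted p = 0.2 with an estimated correlation). The neutrophil list had a median of -1.29 (adjusted p = 0.0211, adjusted p = 0.158 with an estimated correlation), lost without R213G normoxia replicate 1 (adjusted p = 0.0782). NADPH oxidase genes had a median of -0.39 (adjusted p = 0.0441, adjusted p = 0.158 with an estimated correlation), lost without R213G normoxia replicate 1 (adjusted p = 0.0502) or 3 (0.167) or R213G 14-day replicate 1 (0.0702). Ribosomal protein genes had a median of -0.23 (adjusted p = 0.0211, adjusted p = 0.443 with an estimated correlation), lost without R213G normoxia replicate 2 (adjusted p = 0.322) or R213G 14-day replicate 2 (0.351). In all, limma called 656 genes, 356 higher and 300 lower, with 2017 at an unadjusted p under 0.05. The count was 335 without R213G normoxia replicate 2 and 275 without R213G 14-day replicate 3.

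The list of hypoxia-inducible factor targets, genes switched on by low oxygen within cells, passed in none of the 11 comparisons. Against normoxia its adjusted p was 0.653 in WT at 4 days, 0.0902 in WT at 14 days, 0.159 in R213G at 4 days and 0.936 in R213G at 14 days. Of its 14 tested members, the circadian repressor Bhlhe40 was called at 4 days (1.55, adjusted p = 0.000534) and 14 days (1.38, adjusted p = 0.000762) in R213G, and lactate dehydrogenase Ldha at 14 days in WT (1.05, adjusted p = 0.0359). These 2 were named after their values were seen. Of the fits without 1 library of the compared groups, Bhlhe40 kept its calls in all, and Ldha only in that without WT 14-day replicate 1, with 0.222 without WT 14-day replicate 2. The endothelial, epithelial and dendritic cell lists, with 8 tested members each, passed in no comparison either.

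**Figure D3:**
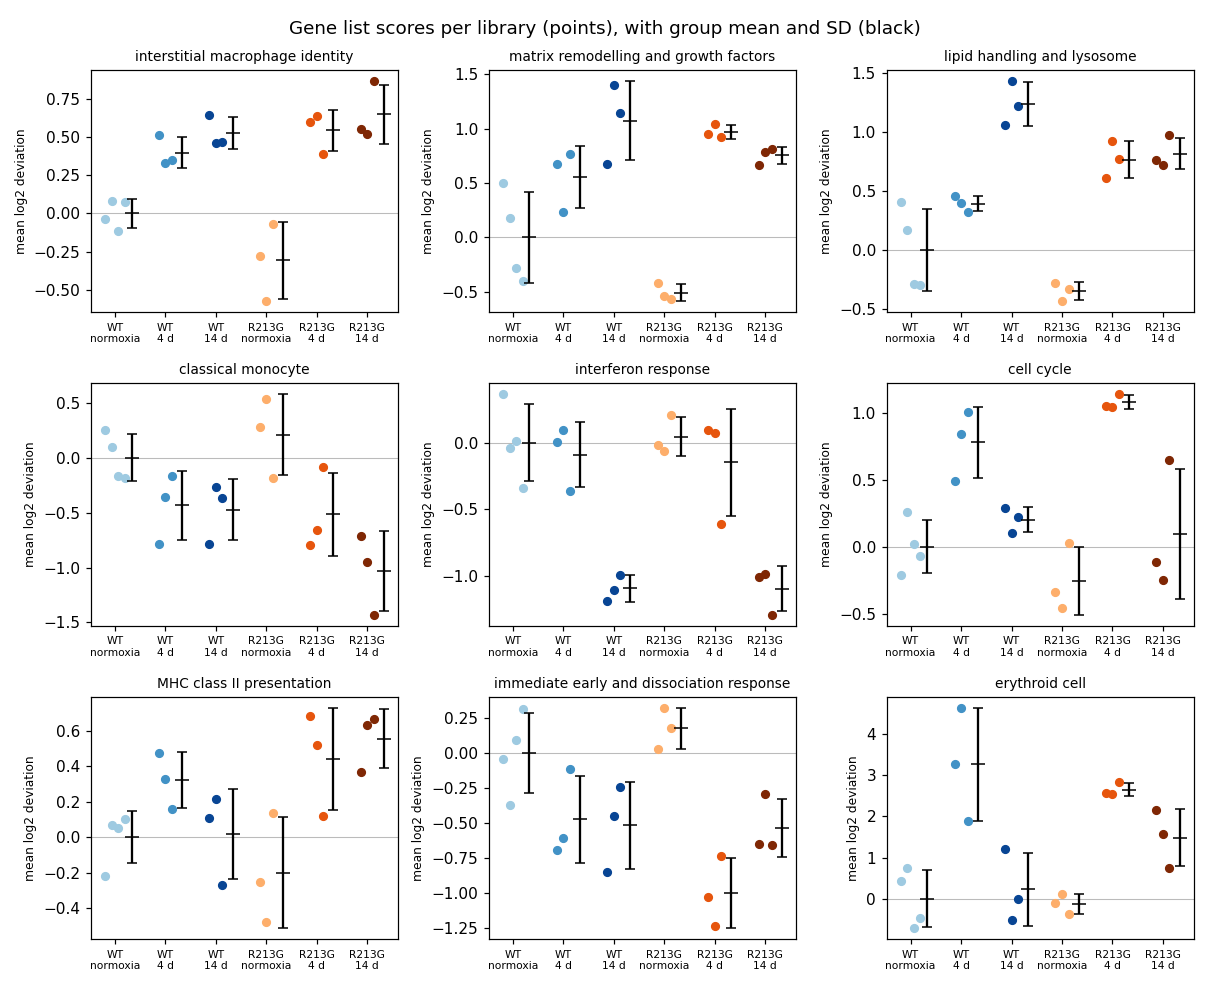
Score of 9 gene lists in each of the 19 libraries, as the mean log2 deviation of the members from the WT normoxia mean, with group mean and SD. The cell cycle score was 1.08 ± 0.052 in R213G at 4 days and 0.778 ± 0.264 in WT at 4 days, and the interferon score was -1.09 in both genotypes at 14 days.

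The comparison of 14 with 4 days in WT asked what changed between the inflammation and resolution times. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) rose from 59.1 ± 8.97 (SD, n = 3) at 4 days to 246 ± 66.5 (SD, n = 3) at 14 days, a log2 fold change of 2.02 (SE 0.263, adjusted p = 0.00106). Ly6e (ENSMUSG00000022587, chromosome 15, 74955051 to 74959905), an interferon-inducible surface protein, fell from 3152 ± 542 to 985 ± 272 (log2 fold change -1.70, SE 0.238, adjusted p = 0.00138). Hba-a2 fell from 624 ± 601 to 46.7 ± 37.96, and erythroid genes fell with 5 of 5 members lower (median -2.90, adjusted p = 1.98e-07, adjusted p = 0.0696 with an estimated correlation). Interferon response genes had 5 of 21 lower and 15 adjusted over the list alone (median -1.19, adjusted p = 4.12e-10, adjusted p = 0.0696 with an estimated correlation). Lipid and lysosome genes had 7 of 13 higher and 9 higher and 1 lower adjusted over the list alone (median 0.78, adjusted p = 1.16e-05, adjusted p = 0.0696 with an estimated correlation). Alveolar macrophage genes had 2 of 12 higher and 8 adjusted over the list alone (median 1.21, adjusted p = 4.31e-05, adjusted p = 0.0696 with an estimated correlation), and NADPH oxidase genes 2 of 6 lower and 3 (median -0.52, adjusted p = 0.00389, adjusted p = 0.0696 with an estimated correlation).

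Glycolysis had a median of -0.56 (adjusted p = 0.0191, adjusted p = 0.13 with an estimated correlation) and cell cycle genes one of -0.74 (adjusted p = 0.0128, adjusted p = 0.396 with an estimated correlation). The glycolysis call was lost without WT 4-day replicate 1 (adjusted p = 0.0826) or 3 (0.0701) or WT 14-day replicate 1 (0.0502). The cell cycle call was lost without WT 4-day replicate 2 (adjusted p = 0.054) or 3 (0.0734). In all, limma called 408 genes, 158 higher and 250 lower, with 2082 at an unadjusted p under 0.05. The count fell to 18 and 11 without WT 14-day replicate 2 and 3 and to 198 without WT 4-day replicate 3. It was 29 in the compared groups alone and 13 with the Gm42418 share, which did not overlap, as a covariate. Upper quartile scaling gave 190 higher and 167 lower genes, and quantile normalization 165 and 149.

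The same comparison was made in R213G. Isg15 fell from 576 ± 106 (SD, n = 3) at 4 days to 100.4 ± 36.4 (SD, n = 3) at 14 days, a log2 fold change of -2.56 (SE 0.324, adjusted p = 0.000624). Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), the matricellular protein thrombospondin 1, fell from 1185 ± 249 to 283 ± 8.45 (log2 fold change -2.04, SE 0.292, adjusted p = 0.00235). Interferon response genes had 4 of 21 lower and 10 adjusted over the list alone (median -0.92, adjusted p = 1.74e-12, adjusted p = 0.0856 with an estimated correlation). Cell cycle genes had 0 of 24 called in either count (median -0.98, adjusted p = 1.68e-08, adjusted p = 0.0856 with an estimated correlation), and the cell cycle score went from 1.08 ± 0.052 to 0.0954 ± 0.486. Classical monocyte genes had 2 of 13 lower and 6 adjusted over the list alone (median -0.50, adjusted p = 0.000227, adjusted p = 0.39 with an estimated correlation). Neutrophil genes had a median of -1.11 (adjusted p = 0.00121, adjusted p = 0.15 with an estimated correlation) and ribosomal protein genes one of -0.38 (adjusted p = 0.000324, adjusted p = 0.441 with an estimated correlation).

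The erythroid list had a median of -1.17 between those times in R213G (adjusted p = 0.0108, adjusted p = 0.441 with an estimated correlation), lost without R213G 14-day replicate 3 (adjusted p = 0.122). Chemokines had a median of -0.58 (adjusted p = 0.0296, adjusted p = 0.39 with an estimated correlation), lost without R213G 4-day replicate 2 (adjusted p = 0.0853) and R213G 14-day replicate 1 (0.0618) or 2 (0.0747). Alternative activation had a median of -0.77 (adjusted p = 0.0296, adjusted p = 0.39 with an estimated correlation), lost without R213G 4-day replicate 1 (adjusted p = 0.0688) or 3 (0.0708) and R213G 14-day replicate 1 (0.0598) or 3 (0.0805). Immediate early genes had a median of 0.31 (adjusted p = 0.00528, adjusted p = 0.492 with an estimated correlation), lost without R213G 4-day replicate 2 (adjusted p = 0.0902) or R213G 14-day replicate 2 (0.065). In all, limma called 38 genes, 16 higher and 22 lower, with 1384 at an unadjusted p under 0.05; DESeq2 called 143. The compared groups alone gave 124 and the Gm42418 covariate 72. Leaving out R213G 4-day replicate 1, 2 or 3 left 4, 2 and 22 calls, and leaving out R213G 14-day replicate 1, 2 or 3 left 15, 2 and 4.

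R213G was compared with WT in normoxia to ask what the genotype changed without hypoxia. No gene passed: limma, edgeR and DESeq2 each called 0, with 432, 528 and 463 genes at an unadjusted p under 0.05 where chance gives 480 in limma. The gene with the smallest p was Igf2r, the receptor that sorts lysosomal enzymes, with 3.36 ± 2.45 (SD, n = 3) normalized counts in R213G and 20.6 ± 11.6 (SD, n = 4) in WT, a log2 difference of -2.28 (adjusted p = 0.182). Mmp14 had 35.8 ± 11.6 in R213G and 123 ± 80.4 in WT (log2 difference -1.60, SE 0.374, adjusted p = 0.913). Matrix remodelling genes had a median log2 difference of -0.48 with 0 of 17 called and 1 lower adjusted over the list alone (adjusted p = 6.06e-05, adjusted p = 0.212 with an estimated correlation). Interstitial macrophage identity genes had a median of -0.30 (adjusted p = 6.06e-05, adjusted p = 0.314 with an estimated correlation), with an adjusted p of 0.127 without R213G normoxia replicate 2. Without that library the other 4 called lists also lost their calls: alveolar macrophage (adjusted p = 0.0231, 0.263 without it), alternative activation (0.0102, 0.16), efferocytosis (0.0158, 0.263) and lipid handling (0.035, 0.184). Their medians were -0.40, -0.45, -0.21 and -0.21, and their adjusted p with an estimated correlation 0.368, 0.324, 0.314 and 0.371. Alternative activation and efferocytosis lost theirs also without WT normoxia replicate 3 (adjusted p = 0.0558 and 0.0992), alveolar macrophage and lipid handling without WT normoxia replicate 1 (0.0617 and 0.169), and lipid handling without WT normoxia replicate 2 (0.134).

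At 4 days, where the question was whether genotype altered the inflamed state, 11 genes differed between R213G and WT, 10 of them lower in R213G. Itgb7 (ENSMUSG00000001281, chromosome 15, 102215995 to 102231944), a leukocyte integrin subunit, was 77.4 ± 29.9 (SD, n = 3) in R213G and 193 ± 6.90 (SD, n = 3) in WT (log2 difference -1.38, SE 0.222, adjusted p = 0.0258). The other lower genes included the transcription factor Rfx2 (-1.63, SE 0.309), the neutrophil-associated surface protein Cd177 (-1.64, SE 0.323) and the autophagy gene Atg7 (-1.09, SE 0.21), each with an adjusted p of 0.0401. Tpgs1, E2f2, Camkk2 and Nfam1 were lower with the same adjusted p, and Nat8l (-1.53, adjusted p = 0.0427) and the one higher gene, Gm14039 (2.96, adjusted p = 0.0401), lie outside the rule and were named after their values were seen. Immediate early genes had a median of -0.36 with 0 of 15 called and 2 lower adjusted over the list alone (adjusted p = 0.000675, adjusted p = 0.705 with an estimated correlation). That list lost its call without WT 4-day replicate 3 (adjusted p = 0.0685) or R213G 4-day replicate 2 (0.06). The count of 11 rested on single libraries: it was 75 without WT 4-day replicate 1, 1 without WT 4-day replicate 2, and 0 without WT 4-day replicate 3, R213G 4-day replicate 1 or R213G 4-day replicate 2. Itgb7 had an adjusted p of 0.0539, 0.115, 0.187 and 0.0984 in the last 4 of these fits. Quantile normalization and a fit of the compared groups alone gave 0, upper quartile scaling gave 1 higher and 1 lower, edgeR called 7 and DESeq2 113, and limma had 1302 genes at an unadjusted p under 0.05.

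At 14 days no gene passed between R213G and WT in limma or edgeR, with 1207 and 1319 genes at an unadjusted p under 0.05, while DESeq2 called 64. Genes with groups that did not overlap made up 22.5% of those tested, where chance gives 10%. The smallest adjusted p was 0.259, shared by many genes, of which those with the smallest unadjusted p in each direction were the transcription cofactor Vgll4 (log2 difference 1.55), the antibody receptor Fcgrt (1.21), Tecr (1.01), Rps27a (-1.46), Sub1 (-0.999) and Tomm7 (-0.97). Ribosomal protein genes had a median of -0.51 with 0 of 20 called and 5 lower adjusted over the list alone (adjusted p = 0.000362, adjusted p = 0.599 with an estimated correlation). The share of Gm42418 was 13.1% to 14.3% in the R213G and 5.96% to 10.7% in the WT libraries at that time. MHC class II genes had a median of 0.51 with 0 of 12 called and 4 higher adjusted over the list alone, led by H2-DMa with 0.95 (adjusted p = 0.000842, adjusted p = 0.599 with an estimated correlation). Classical monocyte genes had a median of -0.62 (adjusted p = 0.00144), erythroid genes 1.34 (0.00629), antioxidant genes -0.46 (0.00629) and lipid handling genes -0.49 (0.00913), each with adjusted p = 0.599 with an estimated correlation. The monocyte call was lost without R213G 14-day replicate 3 (adjusted p = 0.0958), the lipid call without R213G 14-day replicate 1 (0.0616), and the erythroid call without R213G 14-day replicate 1 (0.13) or WT 14-day replicate 2 (0.0688).

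The interaction asked whether the response to hypoxia itself differed by genotype. At 4 days no gene passed in limma or edgeR (700 and 711 genes at an unadjusted p under 0.05), while DESeq2 called 6. Matrix remodelling genes had a median interaction of 0.93 with 0 of 17 called and 1 higher adjusted over the list alone, Mmp14 with 2.21 (SE 0.548; list adjusted p = 2.12e-05, adjusted p = 0.148 with an estimated correlation). Alternative activation genes had a median of 0.90 (adjusted p = 0.000392), lipid handling genes 0.68 (0.000392), chemokines 0.69 (0.00338), interstitial macrophage identity genes 0.43 (0.00038) and immediate early genes -0.40 (1.01e-05), and their adjusted p with an estimated correlation was 0.148 to 0.168. Cell cycle genes had a median of 0.47 (adjusted p = 0.00648, adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, 3 chemokines, 2 lipid genes, 1 alveolar macrophage gene and 1 MHC class II gene were higher, and 2 immediate early genes and 1 NADPH oxidase gene lower. The alveolar macrophage list (median 0.57, adjusted p = 0.00469) lost its call without R213G 4-day replicate 3 (0.0521), NADPH oxidase (-0.22, adjusted p = 0.0135) without WT 4-day replicate 3 (0.0737), and efferocytosis (0.57, adjusted p = 0.00469) without WT 4-day replicate 3 (0.0737) or R213G normoxia replicate 2 (0.0724). With an estimated correlation their adjusted p was 0.16, 0.148 and 0.148.

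The lists of MHC class II (median interaction 0.33, adjusted p = 0.0347, adjusted p = 0.436 with an estimated correlation), Lyve1-high perivascular (0.52, adjusted p = 0.0356, adjusted p = 0.317 with an estimated correlation) and complement genes (0.34, adjusted p = 0.0356, adjusted p = 0.2 with an estimated correlation) rested on more libraries at 4 days. The MHC class II call was lost without WT normoxia replicate 4 (adjusted p = 0.0684), WT 4-day replicate 2 (0.0732) or 3 (0.192), R213G normoxia replicate 1 (0.0672) or 2 (0.24), and R213G 4-day replicate 1 (0.195) or 2 (0.0794). The Lyve1-high call was lost without WT normoxia replicate 2 (adjusted p = 0.0739) or 3 (0.121), WT 4-day replicate 2 (0.0694) or 3 (0.0923), R213G normoxia replicate 2 (0.153) and R213G 4-day replicate 3 (0.141). The complement call was lost without WT normoxia replicate 4 (adjusted p = 0.0684), WT 4-day replicate 1 (0.0524) or 3 (0.192), R213G normoxia replicate 1 (0.058) or 2 (0.184), and R213G 4-day replicate 1 (0.122).

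At 14 days the interaction called no gene in limma or edgeR (1157 and 1294 genes at an unadjusted p under 0.05), while DESeq2 called 78. Limma called 58 genes without R213G normoxia replicate 3. The sodium pump subunit Atp1b3 had an interaction of -1.69 (adjusted p = 0.176), and Vgll4 one of 1.83 (adjusted p = 0.218). MHC class II genes had a median interaction of 0.93 with 0 of 12 called and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.000488, adjusted p = 0.87 with an estimated correlation). Classical monocyte genes had a median of -0.86 (adjusted p = 0.000561, adjusted p = 0.87 with an estimated correlation) and interstitial macrophage identity genes one of 0.50 with 5 higher adjusted over the list alone (adjusted p = 0.00287, adjusted p = 0.87 with an estimated correlation). Ribosomal protein genes had a median of -0.54 with 5 lower adjusted over the list alone (adjusted p = 0.00287, adjusted p = 0.921 with an estimated correlation), with an adjusted p of 0.139 without R213G 14-day replicate 2. Erythroid genes had a median of 1.59 (adjusted p = 0.0458, adjusted p = 0.921 with an estimated correlation). That call was lost without WT normoxia replicate 1 (adjusted p = 0.102) or 2 (0.166), WT 14-day replicate 2 (0.226) or 3 (0.0665), R213G normoxia replicate 3 (0.227) and R213G 14-day replicate 1 (0.247) or 2 (0.0959).

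Set side by side across 9599 genes, the responses of both genotypes shared their direction in part. At 4 days the log2 fold changes of WT and R213G had Pearson's r = 0.416 and Spearman's rho = 0.411. All 57 genes called in both (Fisher's exact test, p = 3.42e-39) shared direction, where independence gives 3.62 such genes. At 14 days r was 0.451 and rho 0.352, and 205 of 206 genes called in both shared direction, where independence gives 19.9. These correlations and that p run across genes, which are not independent replicates. The 639 genes called in R213G at 4 days had a median absolute log2 fold change of 1.14 in R213G and 0.518 in WT, and 599 had the same sign in WT. The 656 called at 14 days had 1.19 in R213G and 0.629 in WT, and 582 had the same sign. Genes picked for their calls in 1 genotype are larger there by selection, and the test of the difference itself is the interaction, which called 0 genes in limma at either time, with 700 and 1157 at an unadjusted p under 0.05, while DESeq2 called 6 and 78. Within a genotype, 24 genes were called in the same direction at both times in WT and 289 in R213G, where independence gives 3.38 and 21.7. These comparisons share their normoxia libraries. In WT, dividing those libraries between the times in 6 ways left 2 to 17 such genes and r of 0.115 to 0.281, against 0.428 with all and 0.433 in data simulated without an effect. In R213G r was 0.624, against 0.496 simulated. The covariance was 0.153 in WT and 0.27 in R213G, against 0.0681 and 0.0885 simulated. The R213G normoxia libraries are too few to divide, so part of its overlap may come from sharing them.

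**Figure D4:**
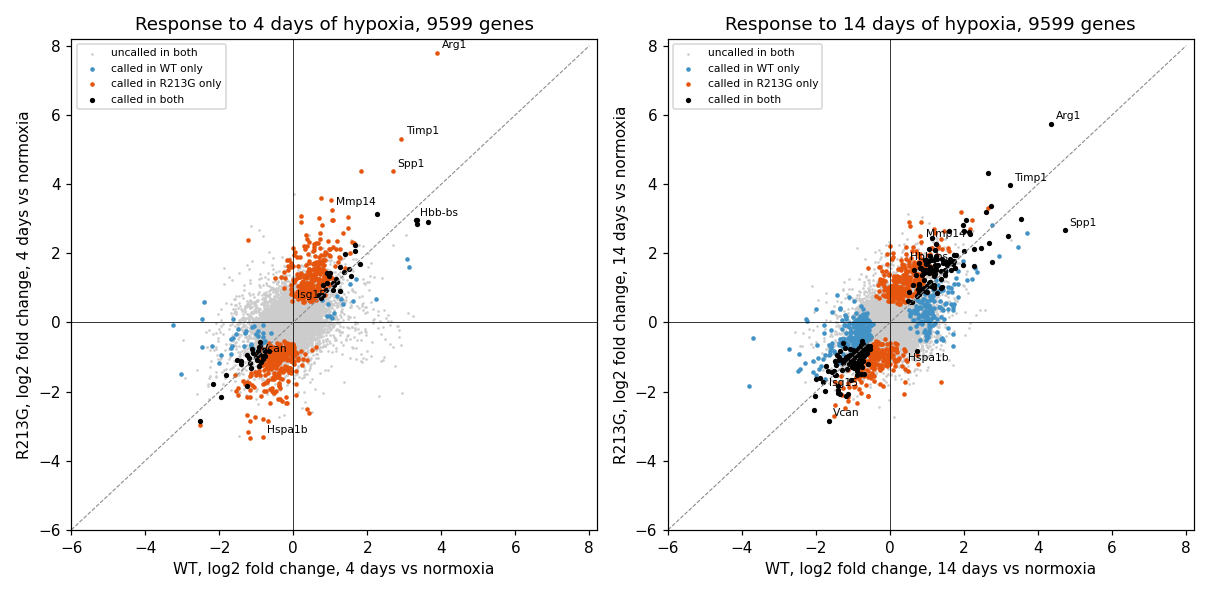
Log2 fold change against normoxia in WT (horizontal axis) and R213G (vertical axis) for 9599 genes at 4 days and at 14 days, coloured by whether a gene was called in WT, in R213G, in both or in neither, with a dashed line where both are equal. The correlation across genes was 0.416 at 4 days and 0.451 at 14 days.

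The labels give each pool 2 male and 2 female mice, and sex-linked transcripts were compared with that. Xist, the transcript of the inactive X chromosome, was 1713 to 2734 normalized counts in 7 libraries that held 0 to 2.64 of the Y-linked helicase Ddx3y. In 10 other libraries Ddx3y was 58.3 to 145 and Xist 0 to 35.4. Both were high in 2 libraries, WT 14-day replicate 1 and R213G 14-day replicate 1, where Xist was 856 to 1006 and Ddx3y 23.9 to 61.7. Each of the 6 groups held libraries high in Xist and libraries high in Ddx3y.

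**Figure D5:**
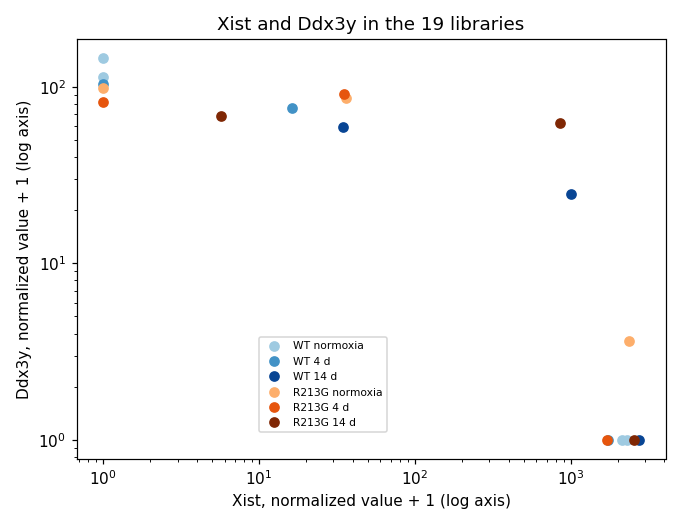
Normalized count plus 1 of Xist (horizontal, log axis) and Ddx3y (vertical, log axis) in the 19 libraries, coloured by group. The points form a set of 7 libraries high in Xist, a set of 10 high in Ddx3y and 2 libraries with both.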

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

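Of the tests in this part, that of the starting level in normoxia and that of the ribosomal RNA share at 14 days were chosen only after the result was seen. Among 77 measures checked over the 4 WT normoxia libraries, 3 held a library far from the others, where chance gives about 1 in 20. Slc7a2 was 40.1 normalized counts in replicate 1 and 4.26 to 7.38 in the others, a gap of 0.913 of the range. Ltc4s, leukotriene C4 synthase, was 11.7 in replicate 2 and 23.4 to 25.4 in the others, a gap of 0.851. The MHC class II score was -0.22 in replicate 1 and 0.053 to 0.10 in the others, a gap of 0.852.

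By the list test of the interaction at the preset correlation, the response to 4 days differed by genotype for 13 lists, some sharing genes. The median interaction was 0.93 for matrix remodelling, 0.90 for alternative activation, 0.69 for chemokines, 0.68 for lipid handling and lysosome, 0.57 for alveolar macrophage, 0.57 for efferocytosis and 0.52 for Lyve1-high perivascular genes. It was 0.47 for cell cycle, 0.43 for interstitial macrophage identity, 0.34 for complement, 0.33 for MHC class II, -0.22 for NADPH oxidase and -0.40 for immediate early genes. The interaction at 14 days passed for 5 lists, with medians of 1.59 for erythroid, 0.93 for MHC class II, 0.50 for interstitial macrophage identity, -0.54 for ribosomal protein and -0.86 for classical monocyte genes. No list kept its interaction call with an estimated correlation, where the smallest adjusted p was 0.148 at 4 days and 0.87 at 14 days.

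Matrix remodelling genes had a mean interaction of 0.92 on the log2 scale at 4 days, towards a larger rise in R213G, with 0 of 17 members called and an adjusted p of 0.148 with an estimated correlation. The tables argue against WT 4-day replicate 1, the library with the fewest reads, as the cause: without it the median interaction was 0.911 (list adjusted p = 7.47e-06). They argue also against different shares of ribosomal RNA reads, since the median was 0.872 with the Gm42418 share as a covariate. The list was lower in R213G than in WT in normoxia by a mean of 0.51 (adjusted p = 6.06e-05, adjusted p = 0.212 with an estimated correlation), and at 4 days it differed by a mean of 0.41 (adjusted p = 0.147). Whether the start in normoxia or the response differed stays open.

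R213G and WT at 14 days had 1207 genes at an unadjusted p under 0.05, with ribosomal protein transcripts lower in R213G by a median of 0.515 on the log2 scale, a list with 0 of 20 members called and an adjusted p of 0.599 with an estimated correlation. Different shares of ribosomal RNA reads may account for much of this, since 586 genes were left at that p with the Gm42418 share as a covariate and the ribosomal median became -0.147. Across genes, the fold change followed the slope on that share within groups with r = 0.433, and 0 of 100 permutations gave one as large. GC content and transcript length stay open, since removing their trend left a ribosomal median of -0.38. The genotype itself stays open too, because the shares of the 2 groups did not overlap.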

How the results depend on the processing

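The fits without the 3 libraries of 676929, 848726 and 849167 reads, with Xist and with the Gm42418 share as a covariate were chosen after seeing the data. Each changed count below is that of called genes, and the cause was not tested except where named. Of 591 results for single genes, 588 kept their direction and side of the threshold with a pseudocount of 0.5, 589 with 4, 570 with edgeR and 521 with DESeq2, which made 61 further calls. Of 124 called list tests, 120 kept their call under quantile normalization, 123 under upper quartile scaling and 35 with an estimated correlation. Against 107 genes in WT at 4 days, DESeq2 called 239, array weights 214, the Gm42418 covariate 204 and no filter 55, and the fit of the compared groups alone, with fewer libraries, 0. Against 589 in WT at 14 days, array weights gave 1214, the deeper libraries alone 931, DESeq2 893, no filter 328 and the Gm42418 covariate 225. For R213G, array weights gave 1510 at 4 days and 1551 at 14 days, and no filter 417 at 4 days. For WT between both times (408 genes), array weights gave 1213, DESeq2 665, the Xist covariate 259, no filter 151, the compared groups alone 29 and the Gm42418 covariate 13. For R213G between both times (38 genes), array weights gave 643, DESeq2 143, the compared groups alone 124, the Gm42418 covariate 72, the filter at 50 gave 62, no filter 19 and the deeper libraries 7. For R213G against WT, no filter gave 1 gene in normoxia. At 4 days (11 genes) array weights gave 437, DESeq2 113, the deeper libraries 23, edgeR 7, no filter 4, the Xist covariate 3, upper quartile scaling 2, and quantile normalization and the compared groups alone 0 each. At 14 days (0 genes in limma) array weights gave 379, DESeq2 64, the compared groups alone 17 and no filter 2. For the interaction, array weights gave 25 and DESeq2 6 genes at 4 days, and 279 and 78 at 14 days. A replicate block by the title number gave 41 genes in WT at 4 days, 295 in WT at 14 days and 0 for R213G against WT at 4 days. A block by the description number gave 55, 243 and 0 for these, and 80 for R213G between both times. Residuals of libraries with the same title number had a median r of -0.0211 over 45 pairs, 6 of them over 0.1, against 0.00764 in other pairs. With the same description number the median was 0.0412 over 36 pairs, 9 of them over 0.1, against -0.00467 in other pairs. Of 19 libraries, 3 correlated best with one of their own title number and 9 with one of their own description number. Pairing by the description number is therefore neither shown nor excluded.

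Leaving out 1 library at a time gave 20 to 141 genes for WT at 4 days, 139 to 559 for WT at 14 days, 290 to 467 for R213G at 4 days, 275 to 600 for R213G at 14 days, 11 to 466 for WT and 2 to 22 for R213G between both times. It gave 0 to 1 for R213G against WT in normoxia, 0 to 75 at 4 days, 0 to 0 at 14 days and for the interaction at 4 days, and 0 to 58 for that at 14 days. The correlation of responses was 0.351 to 0.453 at 4 days and 0.346 to 0.501 at 14 days, and 0.269 at 4 days without the filter, which adds genes of few reads. Sod3 between genotypes in normoxia ranged from -0.717 to 0.156. Sod3, at 3 to 44 reads per library, turned its sign in several fits: in WT at 14 days -0.017 with the Gm42418 covariate, in WT between times 0.23 without WT 4-day replicate 2 (others down to -0.45), and in R213G between times -0.052 without R213G 14-day replicate 1 or 3 (others up to 0.32). Between genotypes at 4 days it became 0.12 without WT 4-day replicate 2 (others down to -0.56). At 14 days it became 0.10 with array weights, 0.040 with edgeR, 0.048 with DESeq2, 0.22 in the deeper libraries or without R213G 14-day replicate 2 and 0.49 with the Gm42418 covariate (others without 1 library down to -0.16). Its interaction at 4 days became -0.40 with array weights, -0.22 with edgeR, -0.21 with DESeq2, -0.034 with the Gm42418 covariate, -0.086 without WT normoxia replicate 2, -0.19 without WT 4-day replicate 3 and -0.41 without R213G normoxia replicate 3. At 14 days it became -0.19 without that last library (others up to 0.68). Mmp8 in R213G between times became 0.021 with array weights and 0.0079 without R213G 4-day replicate 3 (others down to -0.91). Cyba, of the NADPH oxidase, had an interaction at 4 days of 0.017 with quantile normalization, 0.011 with array weights and 0.068 in the deeper libraries.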

Other observations

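Of the tests in this part, those on the sex of the pools were chosen only after the result was seen, and so was the set of genes called in all 4 comparisons with normoxia. That set held 15 genes, 10 higher and 5 lower, of which 10 belong to no list. Ecm1 (ENSMUSG00000028108), an extracellular matrix glycoprotein, had log2 fold changes of 1.51 and 1.55 in WT at 4 and 14 days and 1.54 and 1.74 in R213G, with SE of 0.216 and 0.231. Sparc had 1.80, 1.65, 1.69 and 1.72 in the same order, and the laminin receptor subunit Itga6 1.39, 1.24, 1.99 and 1.61. The myelin protein Pmp22 had 1.26, 1.63, 0.91 and 1.83, and Atpif1, an inhibitor of the mitochondrial ATP synthase, 0.80, 0.77, 0.79 and 0.97. Trem2, C1qc, Timp2, Slc7a2 and Maf were also higher, while Trps1, Pik3r6, Sorl1, Pot1b and Nr4a1 were lower. Ecm1, Sparc, Itga6 and Trem2 stayed called in all 4 whichever of the 19 libraries was left out. Maf stayed so in 5 of 19 such fits (adjusted p = 0.183 in WT at 14 days without WT 14-day replicate 2), Pot1b in 8, Slc7a2 in 9, Atpif1 in 10, Pmp22 in 13 (0.144 in R213G at 4 days without R213G normoxia replicate 2), Pik3r6 in 13 (0.169 in WT at 14 days without WT 14-day replicate 2), Trps1 and Nr4a1 in 14, Sorl1 and Timp2 in 17 and C1qc in 18. The comparisons of 1 genotype share their normoxia libraries.

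Other splits of the same libraries into groups of the same sizes were counted for each comparison. For WT at 4 days, 1 of 35 splits, the real one, gave as many as 107 genes and the highest other gave 20. For WT at 14 days it was 1 of 35, with 589 genes and 85 in the highest other. The share for both, 0.0286, is the smallest that 35 splits can give. It is not adjusted over the 11 comparisons, so it argues against a chance division of the libraries without excluding it. In comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. There the real split gave 639 genes for R213G at 4 days, 656 for R213G at 14 days, 408 for WT and 38 for R213G between both times, and the highest other gave 0 in each, so 1 of the 10 splits was as large. For R213G against WT at 4 days, 2 of 10 splits gave at least 11 genes and the highest other gave 14. Where the real split gave 0 genes, every split is as large and the count tests nothing. That holds for R213G against WT in normoxia (highest other 3, of 35 splits) and at 14 days (1, of 10 splits), and for the interaction at 4 and 14 days (19 and 192, of 100 splits drawn). What set the split with 192 genes apart was not tested.

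The split of Xist and Ddx3y argues against 2 male and 2 female mice in every pool, since only 2 of the 19 libraries held both at over 10% of their highest value. A candidate explanation is that most pools held 1 sex, which no label gives. Sex as the cause of the hypoxia calls is argued against, since 91% of the calls of the 4 comparisons with normoxia were called again with Xist as a covariate and each group held libraries of both kinds. Nnt, which is disrupted in C57BL/6J mice, differed between R213G and WT by -0.20 (SE 0.443) in normoxia, 0.126 (SE 0.473) at 4 days and -0.967 (SE 0.473) at 14 days, with upper 95% bounds of 0.713, 1.11 and 0.0138, so another substrain in the R213G line is neither shown nor excluded.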
